A study of Homo sapiens with 4 samples.

How the data were processed

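RNA was profiled in human lung adenocarcinoma cell lines, CL1-0 and its more invasive derivative CL1-5. Per the labels, 4 stably transduced, puromycin-selected populations were hybridised on 1 Affymetrix array each: CL1-5 with a control shRNA, CL1-5 with a G9a shRNA, CL1-0 with a control vector, and CL1-0 expressing HA-tagged G9a. Total RNA was extracted with a column kit and turned into biotin-labelled cRNA, per the labels' protocols. G9a is the histone H3 lysine 9 methyltransferase encoded by EHMT2.

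The deposited table holds 1 intensity per probe set and array on a linear scale, for 54675 probe sets. MAS5 is the only tool that the submitters' processing notes name; its settings, any scaling target and detection calls are not given in the sources used here. All deposited values were above 0. The arrays had not been brought to a common level. With 2% trimmed from each end, the mean intensity was 93.5 for the CL1-5 control, 121 for the knockdown, 88.6 for the vector and 85.1 for HA-G9a. The median intensities were 11.3, 14.9, 11.7 and 12.3 in that order. MAS5 signals near background are noisy, so ratios of dim genes are less reliable than those of bright ones. With 1 array per group, the number of arrays limits the precision of every value.

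Probe sets were named through the annotation table given with the array, with symbols updated by Entrez identifier against a RefSeq gene table of assembly GRCh38.p14. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were not listed and are unnamed here. Updating matched 41043 of the 41097; the other 54 kept the table's symbol. Probe sets with several symbols named no gene, and 59 probe sets of Y-linked genes and 1 X-linked transcript were left out. This left 19740 genes. A gene's value was that of its single-gene probe set with the highest mean signal over the 4 arrays. Probe sets of near-identical paralogs, such as AKR1C1, AKR1C2 and AKR1C3 or the metallothionein genes, can cross-hybridise, and their single values are uncertain.

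Signals were used as deposited, set to a floor of 3.35 (the 25th percentile of all values of the 4 arrays) and log2-transformed. A gene was counted in a comparison when the brighter of its 2 arrays was at or above 12.5, the median of all values. A stricter filter asked for 84.2, the 75th percentile. Counts used a fixed threshold of 2-fold with no test, since each group had 1 array. The median gene was shifted in both comparisons, so ratios of named genes and of gene lists are given relative to the median log2 ratio of the filtered genes of that comparison, and are called relative. Ratios of EHMT2 and EPCAM are given as deposited first. Where the dimmer array was at or below the floor, the ratio depends on the floor and gives only a lower bound on the size of the difference.

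Named genes followed a rule. For each single-line comparison, the 12 genes with the largest and the 12 with the smallest ratio were taken, among genes past 2-fold whose other measured probe sets had the same sign. For the opposite pattern, the rule took the 12 genes per direction with the largest smaller ratio of the 2 comparisons. Between the lines it took the 12 genes per direction with the largest difference past the threshold. EHMT2, EHMT1 and EPCAM were always named. The endothelial markers VWF, TEK and ERG were named beside the knockdown after their values had been seen. Some genes that the rule names are not reported here. Of each gene list, up to 4 members with the largest absolute ratio could be named. Lists covered pathways and regulators (26 lists) and cell type markers (8 lists). A list is described by its members past 2-fold and by the percentile of its median among 10000 random lists of the same size, matched on mean signal in 20 bins. This describes these arrays and is not a test across replicates. Mean signal was taken over all 4 arrays, so a list that differs between the lines can be set against genes of another brightness. Its percentile may then be too extreme. For the HA-G9a comparison, the 12 genes per direction past the stricter filter were added after the data had been seen.

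Both CL1-5 arrays were compared with both CL1-0 arrays by limma (version 3.58.1, R 4.3.3) with lmFit and eBayes on the log2 values, with 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The 2 arrays of a line are 1 control and 1 perturbed population, so the spread within a line includes the effect of changing G9a. A second limma model had line and G9a arm and left 1 residual degree of freedom. Within each line it set the array with more G9a (the CL1-5 control and HA-G9a) against the array with less. Other steps used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. On simulated data for 13953 genes, with noise from the within-line spread of the real arrays shuffled across genes, the limma step was tested. For the line comparison it recovered 0 of 50 genes changed by 1 on the log2 scale, 0 of 50 at 2, 11 of 50 at 3 and 33 of 50 at 6, with 1 false call; for the arm comparison it recovered 0 of 50 at each size. Of 200 simulated random lists of 20 genes, 4% fell outside the central 95% of random lists matched on signal. The same lists shifted by 1 were compared with random lists not matched on signal, and 100% lay above the central 95% of those.

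Groups, the 2-fold threshold, models, gene lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were median scaling, quantile normalization, a halved or doubled floor, no filter or the stricter filter, the mean over probe sets, leaving out probe sets of types _s_at and _x_at, thresholds of 1.5-fold and 3-fold, eBayes with a mean-variance trend or robust, the arm term in the line model, and the 2 control arrays alone. Median scaling with the stricter filter, and line fits without each array in turn, were added after the data had been seen.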

Results

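The study asked how the level of the histone methyltransferase G9a bears on gene expression in lung adenocarcinoma cells. CL1-5, an invasive subline, was studied with G9a reduced by an shRNA, and CL1-0, its less invasive parent line, with HA-tagged G9a expressed. The 4 groups were CL1-5 with control shRNA, CL1-5 with G9a shRNA, CL1-0 with control vector and CL1-0 with HA-G9a. Each group was 1 array and there were no replicates, so no p-value is given within a line and differences there have no replicate check. Probe sets of the same gene gave a technical yardstick: their log2 ratios differed with a pooled SD of 0.54 in the knockdown comparison and 0.51 in the HA-G9a comparison, and of 0.30 and 0.25 among probe sets past the stricter filter.

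The targeted gene followed the labels. EHMT2, measured by its bright probe set, had a signal of 376 in the CL1-5 control and 28.1 after the knockdown, a log2 ratio of -3.74 as deposited and -4.16 relative to the median gene. In CL1-0 its signal was 420 with the vector and 862 with HA-G9a, a log2 ratio of 1.04 as deposited and 1.12 relative. Scaled to one median the ratio was 0.963, just below 2-fold. Both control populations thus had similar EHMT2 signals. A dimmer probe set went from 34.2 to 9.98 after the knockdown and from 38.0 to 44.2 with HA-G9a. The remaining probe set stayed between 2.10 and 7.89 on all arrays, below the filter. EHMT1, which encodes the partner methyltransferase GLP, had signals of 377 and 463 in CL1-5 and of 309 and 231 in CL1-0, relative log2 ratios of -0.12 and -0.34.

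EPCAM, an epithelial adhesion gene that G9a is reported to repress, was dim on all arrays. It is the gene this study is known for, so its ratios here may not be an independent check. Its single probe set read 6.06 in the CL1-5 control and 18.1 after the knockdown, a log2 ratio of 1.58 as deposited and 1.16 relative. In CL1-0 it read 24.6 with the vector and 12.6 with HA-G9a, a log2 ratio of -0.97 as deposited and -0.88 relative. The signals ran opposite to EHMT2 in both lines, at levels close to the median of all probe sets, 12.5, where MAS5 signals are noisy.

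**Figure D1:**
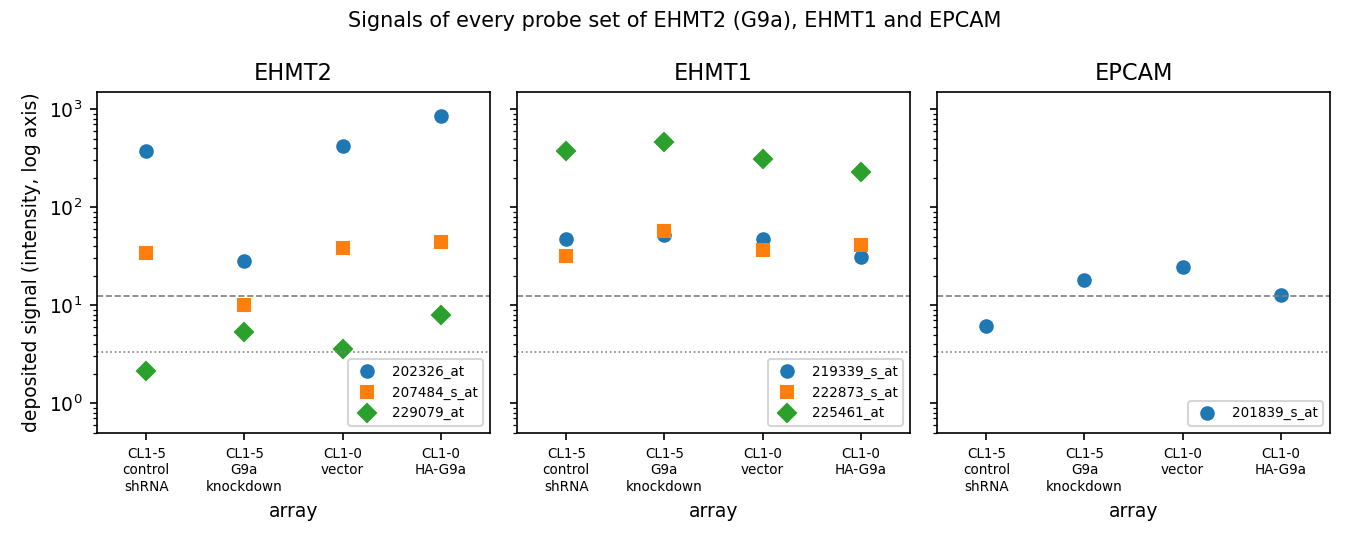
Deposited signals (intensity, log axis) of every probe set of EHMT2, EHMT1 and EPCAM on the 4 arrays, with 1 symbol per probe set; the dashed line marks the filter of 12.5 and the dotted line the floor of 3.35. The bright EHMT2 probe set reads 28.1 after the knockdown against 376 in the control, and 862 with HA-G9a against 420 with the vector.

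Reducing G9a in CL1-5 went with large differences in aldo-keto reductases and interferon-stimulated genes, and in single genes of the extracellular matrix. Of the aldo-keto reductases of steroids and xenobiotics, whose probe sets can cross-hybridise, AKR1C2 read 2271 against 8.20 in the control, AKR1C3 2015 against 8.52, and AKR1C1 2114 against 21.1. Among the genes far dimmer after the knockdown, SULF2, a heparan sulfate endosulfatase, read 0.83 against 604, and TIMP3, a matrix-bound metalloproteinase inhibitor, 47.8 against 1976. SPARC, a matricellular glycoprotein, read 4.73 against 283.

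Further genes among the 12 with the largest ratios were AGR2, a protein disulfide isomerase of secretory epithelia (relative log2 ratio 7.26), PLCB1, a phospholipase C (5.82), KYNU, an enzyme of tryptophan breakdown (5.78), and F2RL2, a protease-activated receptor (5.64). The ion channel gene TRPA1 had a ratio of 5.63, CYP1B1 5.29, the growth factor gene NRG1 5.00 and the adhesion receptor gene ADGRG6 4.96. The control signals of PLCB1, KYNU and F2RL2 were at or below the floor. At the other end stood SRGN, a secretory granule proteoglycan (-6.61), EGFLAM (-6.13), BCL2A1, an anti-apoptotic BCL2 family member (-6.10), and MAML2, a Notch coactivator (-5.88). HIC1, a transcriptional repressor, had a ratio of -5.75, ANXA3 -5.61, SIRPA -5.23, PTX3, a soluble pattern recognition protein, -5.22, and the GABA receptor gene GABBR2 -5.21. In the knocked-down cells SULF2, SRGN, EGFLAM, BCL2A1, HIC1 and ANXA3 were at or below the floor.

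By count, 2198 genes were at least 2-fold higher and 618 at least 2-fold lower after the knockdown as deposited, of 13045 filtered genes. The knockdown array was brighter across most genes, and the median gene had a log2 ratio of 0.42, a fold of 1.34. Relative to that median, 1060 genes were higher and 1012 lower. Ratios taken relative to the median gene remove any general rise, whether of the array or of the cells. With the arrays scaled to one median the split was 950 higher and 1081 lower, and after quantile normalization 946 and 1058. The 18 bacterial hybridization control probe sets had a median log2 ratio of 0.11 (SD 0.11 between probe sets), against 0.41 for genes of the same brightness. Past the stricter filter, 408 genes were higher and 441 lower relative to the median gene, of 8458, and 82 and 148 passed 4-fold. Of the genes past the stricter filter in the control, 75 were at least 8-fold lower. Among the 43 genes at least 32-fold brighter in CL1-5 than in CL1-0, the median relative log2 ratio after the knockdown was -0.26 (SD 0.99). The CL1-5 level there included the knockdown array, so genes lost after the knockdown tended to be left out. SULF2 read 604 in the control and 10.6 with the vector, yet its log2 difference between the lines was 2.06. The small median thus does not show that genes bright in CL1-5 were spared.

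Interferon-stimulated genes were lower together. Of 29 measured members, 21 were at least 2-fold lower and 0 higher, with a median relative log2 ratio of -2.45, below all 10000 random lists. OAS2, an activator of RNase L, read 1.72 after the knockdown against 79.0 in the control. IFIT3 read 26.5 against 529, MX1, an antiviral GTPase, 6.09 against 118, and IFIT2 had a relative log2 ratio of -4.35. NF-kB cytokines and chemokines were lower as well, with 8 of 14 lower, 1 higher and a median of -1.03, also below all random lists. CCL5, a T cell chemoattractant, read 1.04 against 60.8, CXCL1 80.8 against 151, and IL11 had a ratio of -2.85, whereas CXCL3 read 45.0 against 13.6.

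Xenobiotic and NRF2 targets were higher. Of 19 measured members 11 were higher and 0 lower, with a median of 1.20, above all random lists; AKR1C2, AKR1C3, AKR1C1 and CYP1B1 had the largest ratios, and probe sets of the 3 AKR1C genes can share signal. Of 6 measured metallothioneins, 5 were higher and 0 lower (median 1.19, above all random lists), led by MT1E at 845 against 149 and MT1F at 835 against 190. These genes are also near-identical paralogs and single members are uncertain. SLC7A11, the cystine transporter placed in the ATF4 list, read 1929 against 237.

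Of 25 measured mesenchymal genes, 12 were lower and 4 higher, with a median of -0.83, below all random lists. SPARC was joined by ITGB3, the beta chain of the vitronectin receptor, at 17.5 against 367. Against that direction, S100A4, a calcium-binding protein linked to motility, read 2178 against 188, and TCF4, an E-protein, had a ratio of 3.22. Among extracellular proteases and inhibitors 6 of 21 were lower and 1 higher (median -0.13, percentile 16.9): MMP1 read 16.8 against 424 and MMP14, a membrane-type metalloproteinase, 102 against 423, with TIMP3 lowest. ADAMTS1 read 1.47 against 12.6. Of 6 measured genes tied to CL1 invasion in earlier work, 3 were lower and 0 higher (median -0.70, percentile 0.84); CRMP1 read 2.76 against 16.1 and SNAI2, the EMT transcription factor Slug, 274 against 682. L1CAM had a ratio of -1.05 and DNAJB4 of 0.56. PLAU and CXCL8, named in other comparisons, had ratios of -0.15 and -0.34 after the knockdown.

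Epithelial genes were mixed, with 5 of 22 higher and 4 lower (median 0.28, percentile 95.6). CLDN3, a tight junction claudin, read 88.4 against 1.05 and CDH1, which encodes E-cadherin, 77.6 against 2.36. The second CDH1 probe set was below the filter on both CL1-5 arrays, at 1.14 against 5.59. The desmocollin gene DSC2 read 11.1 against 35.5 and KRT8 325 against 757. Of 6 measured genes that G9a repressed in earlier work, 3 were higher and 0 lower (median 0.63, percentile 98.0): CDH1, EPCAM and CASP1, the last at 34.4 against 12.6 with 1 of its 2 measured probe sets of the other sign. EPCAM is the gene this study is known for, so its place on the list may not be independent of these arrays. APC2 had a ratio of -0.42.

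Of 12 measured imprinted genes, 3 were higher and 0 lower (median 0.73, percentile 99.98). PEG10 and its neighbour SGCE read 919 against 50.3 and 625 against 106, and NNAT read 15.3 against 1.60. Cancer-testis genes, often silenced by DNA methylation, had 1 of 11 higher and 0 lower (median -0.08, percentile 33.8); MAGEB2 read 65.7 against 15.7. Of 26 genes of the H3K9 and DNA methylation machinery, 3 were lower and 0 higher (median -0.14, percentile 12.3): EHMT2, SETDB2 (-1.36, with 1 of 2 measured probe sets of the other sign) and ZNF644 (-1.12), the zinc finger partner of the G9a complex. CDYL had a ratio of -0.99.

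In the Wnt list 4 of 13 genes were lower and 2 higher (median -0.42, percentile 2.51). SFRP1, a secreted Wnt antagonist, read 238 against 1363, with 1 of its 4 measured probe sets of the other sign; DKK3 had a ratio of -1.81, LEF1 of -2.86, and AXIN2, a feedback target of Wnt signalling, read 50.2 against 7.62. Of 20 TGF-beta and YAP targets 4 were higher and 4 lower (median 0.28, percentile 99.3): ID2, an inhibitor of bHLH factors, read 529 against 51.4, TGFB1 151 against 582, LTBP2 37.4 against 103 and INHBA 0.41 against 15.3. Immediate early genes also split 4 against 4 of 21 (median 0.04, percentile 63.6): HBEGF, an EGF receptor ligand, read 223 against 1587, the phosphatase gene DUSP1 273 against 1336 and ATF3 8.45 against 64.2, while EREG read 32.3 against 1.46. Of 22 serine, glycine and ATF4 targets, 6 were lower and 2 higher (median -0.43, percentile 0.01), with DDIT4 at 125 against 314 and VLDLR at 9.05 against 24.4.

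Integrins and laminins had 4 of 17 lower and 1 higher (median -0.19, percentile 10.5): LAMB1 read 56.5 against 448, CD44, the hyaluronan receptor, 653 against 1581, CD82 13.8 against 64.3 and LAMA5 118 against 26.3. Of 5 measured keratin and cornified envelope genes, 3 were higher and 1 lower (median 1.12, percentile 99.6), with KRT80 at 121 against 11.1, SFN at 309 against 76.9 and TGM2, tissue transglutaminase, at 15.4 against 236. REST-repressed neuronal genes had 5 of 18 higher and 6 lower (median 0.09, percentile 75.2), with NEFM at a ratio of 2.48 and SNAP25 at 10.9 against 40.8. Of 18 p53 targets 2 were higher and 2 lower (median 0.22, percentile 93.4): GADD45A read 338 against 1755 and GDF15 113 against 19.4. Autophagy and lysosome genes had 2 of 19 lower and 0 higher (median -0.07, percentile 33.3), namely BECN1, a core autophagy gene, at 153 against 474, and WIPI1 at 44.9 against 128.

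The remaining lists stayed near the median gene. Of 22 hypoxia and glycolysis genes 2 were higher and 1 lower (median -0.16, percentile 10.4), the lower being HK2, hexokinase 2, at 188 against 644. Of 14 cholesterol synthesis genes 0 were higher and 1, SC5D, was lower at 205 against 498 (median 0.00, percentile 49.3). None of 32 cell cycle genes passed 2-fold (median 0.04, percentile 91.4), none of 17 unfolded protein response genes (median -0.21, percentile 4.52) and none of 12 ribosomal protein genes (median -0.26, percentile 4.18).

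Markers of cell types differed from list to list. All 5 measured endothelial markers were at least 2-fold lower (median -2.78, percentile 0.01): PECAM1 read 81.5 against 318, CLDN5 7.87 against 81.8, CDH5 5.24 against 62.3 and KDR 3.27 against 17.2, whereas VWF, at 1.97, and TEK, at 1.86, were at background in the CL1-5 control. Of 11 type II alveolar markers 2 were higher and 2 lower (median -0.30, percentile 9.89); HOPX read 12.2 against 97.9 and NKX2-1, the lung lineage factor, 3.87 against 29.6. Type I alveolar markers had 1 of 5 lower and 0 higher (median -0.40, percentile 5.96). Of the airway, basal, fibroblast, leukocyte and neuroendocrine lists, the numbers measured were 3, 1, 2, 3 and 1. Past 2-fold were BPIFA1 of the airway list (-1.49), COL1A1 of the fibroblast list (1.79, with 1 of 3 measured probe sets of the other sign), LCP1 of the leukocyte list (-1.01) and SYP of the neuroendocrine list at 27.8 against 10.4. KRT15, the only basal marker measured, had a ratio of -0.53.

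**Figure D2:**
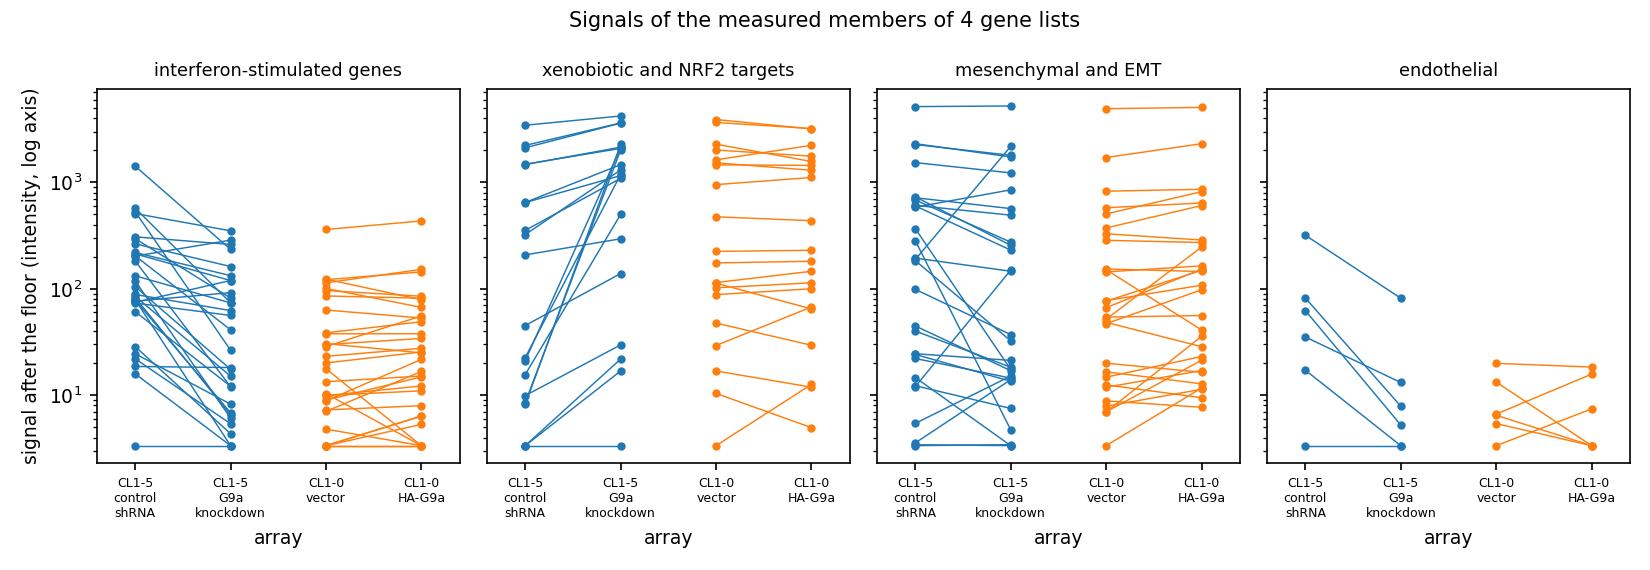
Signals after the floor (intensity, log axis) of the measured members of 4 gene lists; each line joins a gene's values on the 2 arrays of CL1-5 (blue) and of CL1-0 (orange). Interferon-stimulated genes had a median relative log2 ratio of -2.45 after the knockdown and xenobiotic and NRF2 targets of 1.20.

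HA-G9a in CL1-0 went with smaller differences. Among the brighter genes, CD44 read 331 with HA-G9a against 32.3 with the vector, PLAU, which encodes the urokinase plasminogen activator, 145 against 17.2, and LAMB3, a laminin chain, 188 against 25.1. MET, the hepatocyte growth factor receptor, read 883 against 146 and SOX9, a lung progenitor transcription factor, 191 against 30.8. CXCL8, which encodes interleukin-8, read 36.4 against 4.46. Dimmer with HA-G9a were COL3A1, a fibrillar collagen, at 59.7 against 330, the neuropeptide gene NTS at 132 against 565, and the stress genes CHAC1 at 38.4 against 220 and DDIT3 at 89.2 against 300.

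Among the 12 highest ratios were P3H2, a collagen prolyl hydroxylase (4.84), IGFBP3 (3.86), C19orf33 (3.81), DACT1 (3.64), PADI3 (3.62), CLDN4 (3.29), the chemokine gene CCL2 (3.26), CRYBG1 (3.24), DEFB124 (3.22) and ZNF462 (3.21), beside CD44 (3.44) and PLAU (3.16). The vector signals of P3H2, C19orf33, PADI3, CLDN4, CRYBG1 and ZNF462 were at or below the floor. Among the 12 lowest were C4orf54 (-5.50), KCNJ2 (-3.23), ZNF771 (-3.21), ANKRD24 (-3.17), BCAS3 (-3.05), TSNARE1 (-3.04), PCDHB18P (-3.01), TMT1A (-3.01), SLIRP-OT1 (-2.97), SPRR2B (-2.86) and KLK4 (-2.80). Of these only C4orf54 and TMT1A had a vector signal above 84.2, at 160 and 101. The HA-G9a signals of C4orf54, KCNJ2, ZNF771, BCAS3, TSNARE1, PCDHB18P, SLIRP-OT1, SPRR2B and KLK4 were at or below the floor, so their ratios and order depend on it. ZNF771 and TMT1A were measured only by probe sets of types _s_at or _x_at, as their other probe sets were at or near the floor. Among genes past the stricter filter the higher end also held UCA1, a long noncoding RNA (2.69), PHLDB2 (2.47), TGFBI, a TGF-beta-induced matrix protein (2.33), TMEM158 (2.33), the kinase gene SGK1 (2.25) and GPRC5A (2.24). The lower end held VGLL3 (-2.78), POSTN, which encodes periostin (-1.80), UBALD2 (-1.75), SESN2 (-1.73), SLC25A21 (-1.65) and the Notch target HEY1 (-1.64).

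By count, 611 genes were at least 2-fold higher and 569 lower as deposited, of 12791. The median gene had a log2 ratio of -0.08, and relative to it 699 were higher and 479 lower. The split turned with the scaling: it was 553 higher and 705 lower with the arrays scaled to one median, and 652 and 642 after quantile normalization. Past the stricter filter, 121 of 7743 genes were higher and 64 lower relative to the median gene, and 27 and 6 passed 4-fold, so most genes past 2-fold were dim. The split past this filter also turned with the scaling, at 102 higher and 94 lower as deposited and 86 and 122 with median scaling. The hybridization controls had a median log2 ratio of -0.32 (SD 0.13). Among genes with a signal of at least 1000, log2 ratios had an SD of 0.67 over 1582 genes in the knockdown comparison and of 0.25 over 1094 genes in the HA-G9a comparison, a ratio of 2.68.

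Lists on adhesion, proteolysis, CL1 invasion and AP-1 had medians near or above the highest of the random lists with HA-G9a. Integrins and laminins had 7 of 16 higher and 0 lower (median 0.29, percentile 99.9), with CD44 and LAMB3 joined by ITGA2, at 43.9 against 5.66, and CD82, at 38.8 against 7.76. Extracellular proteases had 8 of 22 higher and 0 lower (median 0.45, percentile 99.99): besides PLAU, MMP1 read 27.3 against 3.98, MMP2 38.1 against 6.90 and TFPI2, a serine protease inhibitor, 240 against 71.4. Of 6 measured CL1 invasion genes 3 were higher and 0 lower (median 1.33, above all random lists), namely PLAU (3.16), CXCL8 (3.11) and SNAI2 (2.45). The other 3 members lay near 0, CRMP1 at -0.22, so no gene lay near the median, and the list mixes promoters of invasion with suppressors such as CRMP1. Immediate early genes had 7 of 20 higher and 1 lower (median 0.39, above all random lists), with PHLDA1 at 564 against 136, the AP-1 subunit FOSL1 at 214 against 60.8, DUSP4 at 22.8 against 4.39 and FOS at 13.0 against 1.69. TGF-beta and YAP targets had 6 of 19 higher and 0 lower (median 0.29, percentile 99.98): THBS1, thrombospondin 1, read 391 against 97.4, TGFB2 85.6 against 34.5, TGFBR2 84.9 against 34.2 and ANKRD1 17.5 against 5.77.

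Mesenchymal genes had 6 of 25 higher and 1 lower (median 0.27, percentile 99.7): SNAI2 read 35.7 against 6.93, TGFBI 246 against 51.7 and CDH2, which encodes N-cadherin, 21.3 against 6.98, while POSTN read 41.0 against 151. Epithelial genes had 4 of 24 higher and 3 lower (median 0.07, percentile 74.5), with the keratins KRT18 at 2113 against 545 and KRT8 at 186 against 67.1, and CRB3, a polarity gene, at 3.45 against 19.7. Of 7 keratin and cornified envelope genes 4 were higher and 0 lower (median 1.39, percentile 99.9), including KRT80 at 63.1 against 12.6. NF-kB cytokines had 4 of 12 higher and 1 lower (median 0.36, percentile 95.6); CCL2 read 42.0 against 4.64, CXCL2 18.5 against 6.02 and ICAM1 30.6 against 12.2. Interferon-stimulated genes had 3 of 20 higher and 1 lower (median 0.30, percentile 99.3): IFIT3 read 21.7 against 8.84, IFIT2 16.7 against 7.05 and IFIT5 55.5 against 28.6, while IFI44L read 3.21 against 17.7.

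Of 23 measured serine, glycine and ATF4 targets, 5 were lower and 0 higher (median -0.35, below all random lists). CHAC1 was followed by SESN2, at 112 against 392, DDIT3 and STC2, at 21.1 against 47.9. Unfolded protein response genes, which share upstream sensors with ATF4, had 0 of 17 past 2-fold (median 0.05, percentile 72.5); CALR read 700 against 1411, a relative log2 ratio of -0.93.

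Imprinted genes had 2 of 12 higher and 0 lower (median 0.24, percentile 97.6), PHLDA2 at 375 against 88.2 and NNAT at 17.8 against 1.88. Other lists had few members past 2-fold. The H3K9 and DNA methylation machinery had 1 of 26 higher, EHMT2 itself (median 0.02, percentile 60.5). G9a-repressed genes had 1 of 6 higher and 0 lower (median -0.16, percentile 22.5), CASP1 at 13.8 against 1.91. Cancer-testis genes had 1 of 11 higher (median -0.13, percentile 13.6), p53 targets 1 of 17 higher and 1 lower (median -0.01, percentile 50.6), and Wnt genes 1 of 10 higher (median 0.10, percentile 74.6), the Wnt antagonist DKK1 at 187 against 45.8. Neuronal REST targets had 1 of 18 higher (median 0.11, percentile 87.7), hypoxia genes 2 of 21 higher (median 0.10, percentile 92.0) and xenobiotic and NRF2 targets 2 of 19 higher (median 0.07, percentile 83.0). No metallothionein of 6 (median 0.33, percentile 99.1), cell cycle gene of 32 (median -0.03, percentile 26.1), autophagy gene of 19 (median 0.03, percentile 66.5), cholesterol synthesis gene of 14 (median -0.03, percentile 34.4) or ribosomal protein gene of 12 (median 0.01, percentile 62.9) passed 2-fold.

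Of the cell type markers, type I alveolar genes had 2 of 4 higher (median 0.98, percentile 99.9), including CAV1, caveolin 1, at 1820 against 836. Type II markers had 2 of 8 higher and 1 lower (median -0.04, percentile 41.9), with SFTPC at 6.72 against 21.3. Fibroblast markers had 1 of 4 lower, COL3A1, and 0 higher (median -0.44, percentile 11.9). Endothelial markers had 1 of 3 higher, TEK, and 1 lower, PECAM1, with 1 of its 2 measured probe sets of the other sign (median -0.03, percentile 47.0), and neuroendocrine markers 1 of 3 higher, CALCA at 16.5 against 3.21 (median 0.05, percentile 48.0). The 2 leukocyte markers measured did not pass 2-fold, nor did the airway marker MUC5AC (0.95), while the basal marker KRT15 read 23.3 against 3.36.

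**Figure D3:**
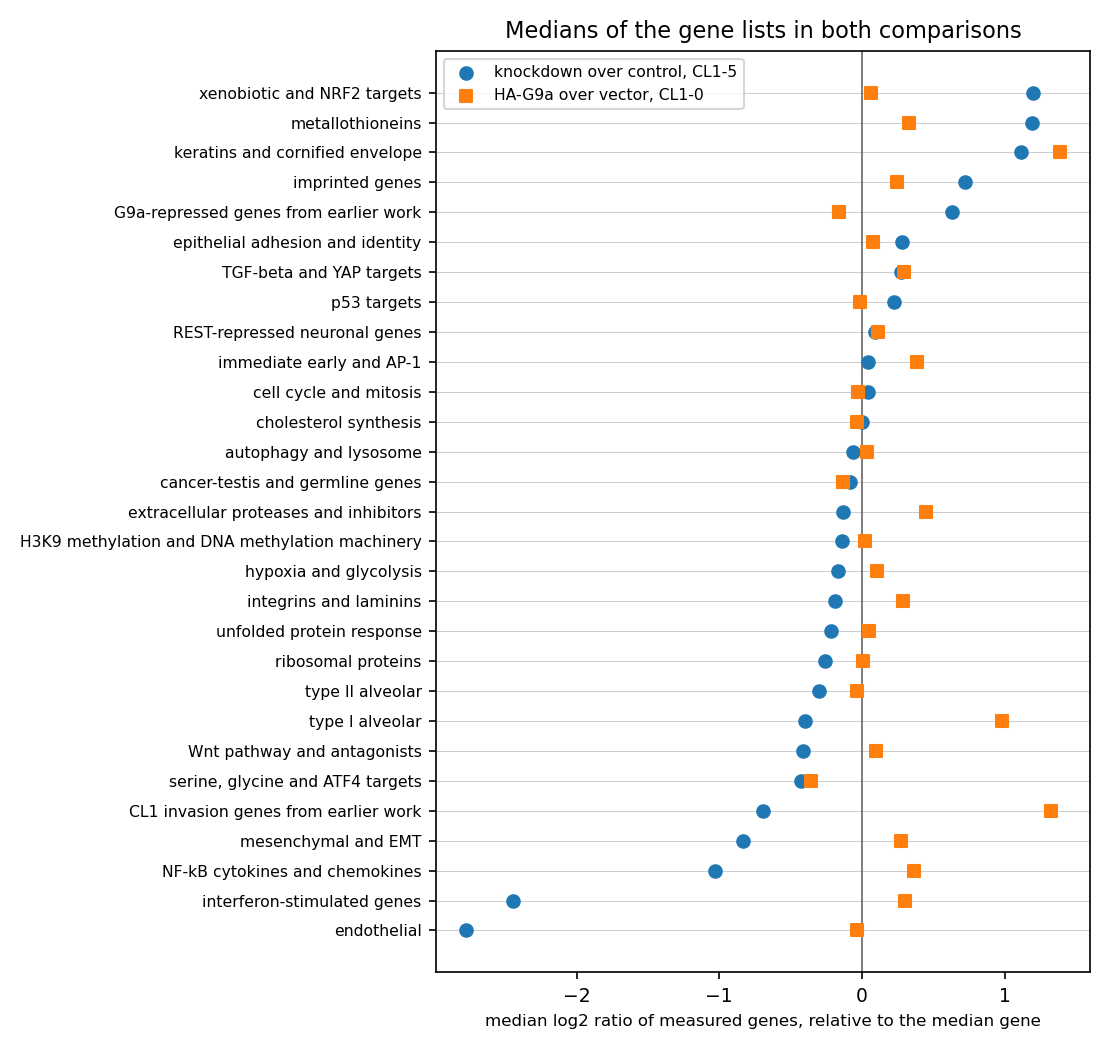
Median relative log2 ratio of each gene list with at least 3 measured genes in both comparisons, for the knockdown over its control (circles) and HA-G9a over its vector (squares). Interferon-stimulated genes lie at -2.45 and 0.30, CL1 invasion genes at -0.70 and 1.33. Of the CL1 invasion genes only SNAI2 was past 2-fold in both comparisons.

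Genes whose ratios ran opposite in the 2 lines were compared next, since the perturbations change G9a in opposite directions. The 12 genes lower after the knockdown and higher with HA-G9a were ranked by the smaller absolute ratio of the 2 comparisons. MMP1, interstitial collagenase, had relative log2 ratios of -5.08 after the knockdown and 2.86 with HA-G9a. PTX3 had -5.22 and 2.58, and NRP2, a semaphorin and VEGF coreceptor, -5.17 and 2.30. Another measured NRP2 probe set went the other way with HA-G9a, at 11.9 against 14.6. The tetraspanin gene CD82 had -2.63 and 2.40, AFAP1L1 -2.61 and 2.26, EVA1A -3.57 and 2.10, and SPOCD1 -3.83 and 2.08. ZNF462, SPTBN5, PICSAR, TNXB and RBP3 completed the 12. All 12 were dim in CL1-0: the brightest, CD82, read 38.8 with HA-G9a, and MMP1 read 27.3 against 3.98. The vector signals of PTX3, ZNF462, SPTBN5, PICSAR, EVA1A, TNXB and RBP3 were at or below the floor. TGFBI (-1.80 and 2.33), TMEM158 (-2.04 and 2.33), SGK1 (-2.24 and 2.25), SOX9 (-1.15 and 2.71) and CD44 (-1.70 and 3.44), named above by the stricter filter, ran the same way.

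In the other direction, higher after the knockdown and lower with HA-G9a, stood CCNG2, an atypical cyclin, at 467 against 97.8 in CL1-5 and 57.7 against 215 in CL1-0. ERBB3, a receptor of the EGF receptor family, read 13.3 against 0.67 and 8.56 against 50.3. OVOL2, a factor of epithelial identity, was dim, at 14.8 against 1.88 and 3.36 against 12.5; its other probe set was below the floor on all 4 arrays, so the ratios rest on 1 probe set. SLC25A21 read 84.3 against 12.4 and 42.2 against 141. C21orf58, SLC6A17, NEU4, GAD2, NPY, VASH1-AS1, LINC01551 and YPEL1 had brightest signals of 56.3, 43.9, 22.9, 15.0, 17.2, 19.8, 50.2 and 44.2, all dim; with HA-G9a, C21orf58 reversed without probe sets of types _s_at and _x_at and GAD2 in the mean over probe sets.

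As deposited, 77 genes were lower after the knockdown and higher with HA-G9a, against 15.6 for independent lists, and 93 were higher and lower, against 56.0. Genes past 2-fold the same way were in excess too, with 115 higher in both against 62.9 and 38 lower in both against 13.9. Relative to the median gene, 125 genes were lower and then higher against 32.4, 49 higher and then lower against 19.7, 87 higher in both against 32.3, and 44 lower in both against 19.7, of 11883 genes. Past the stricter filter the counts, still relative to the median gene, were 30 against 3.72, 5 against 0.996, 13 against 3.28 and 2 against 1.13, of 7317 genes. As deposited, 19 genes past this filter were lower and then higher and 12 higher and then lower, so the balance of the 2 directions depends on the scaling. Across genes, which are not independent replicates, the 2 ratios had a Pearson correlation of -0.04 and a Spearman correlation of -0.04, and of -0.07 and -0.06 past the stricter filter.

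**Figure D4:**
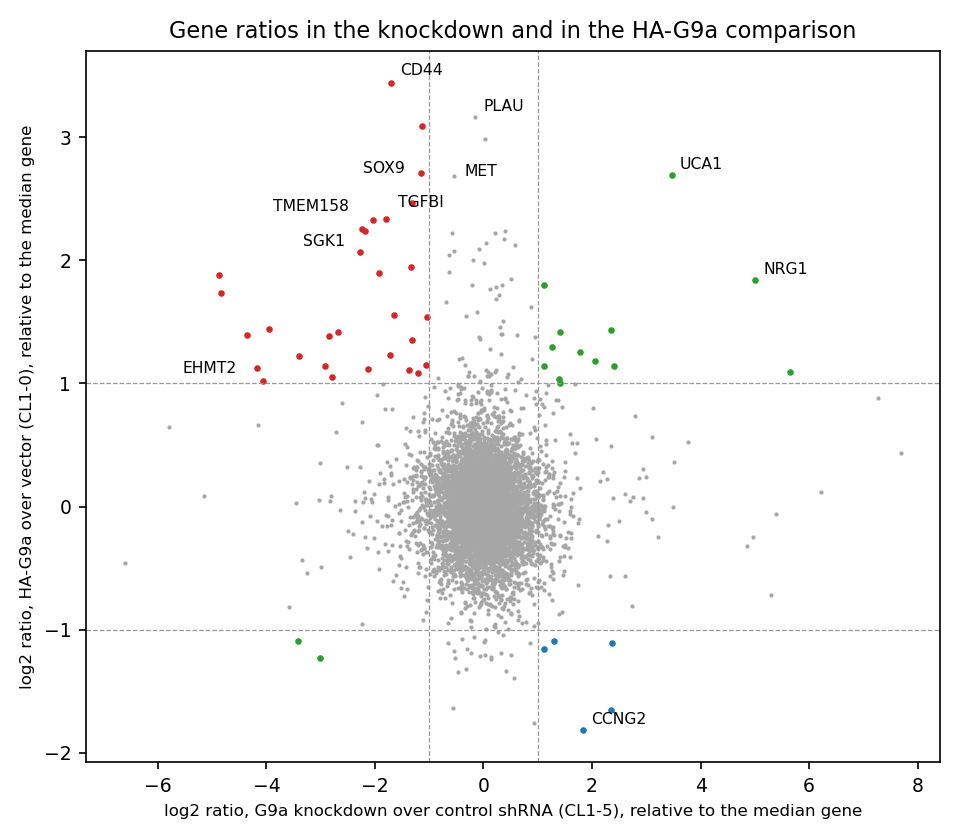
Relative log2 ratio of each of 7317 genes past the stricter filter in both lines, after the knockdown in CL1-5 (horizontal) and with HA-G9a in CL1-0 (vertical); dashed lines mark 2-fold. Red points are the 30 genes lower and then higher, blue the 5 higher and then lower, and green the 15 past 2-fold the same way.

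The cell lines were compared with limma over 2 arrays each, 13953 genes being tested. Some transcripts abundant in CL1-0 were far dimmer in CL1-5: GJA1, which encodes the gap junction protein connexin 43, had a mean log2 signal of 2.01 ± 0.37 (SD, n = 2) in CL1-5 and 11.66 ± 0.06 in CL1-0, a difference of -9.65 (SE 0.34, limma adjusted p = 0.00496). ALDH1A1, a retinaldehyde dehydrogenase, differed by -9.14, and SOX2, a stem cell and lung lineage factor, by -7.98. In the other direction MALL, a raft-associated proteolipid, had 10.17 ± 0.11 in CL1-5 and the floor value of 1.75 on both CL1-0 arrays, a difference of 8.42 (SE 0.30, limma adjusted p = 0.00496). Where both arrays of a line were at the floor, as for MALL in CL1-0 and ALDH1A1 in CL1-5, that line's spread was 0 by construction. GJA1 read 0.28 and 4.81 on the CL1-5 arrays, and the lower value was raised to the floor, which narrowed its SD. The SE and p-value of all such genes rest partly on the floor. CXCL8 differed by 7.03 (limma adjusted p = 0.0397).

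At a limma adjusted p under 0.05, 199 genes were higher and 207 lower in CL1-5, and 2866 had an unadjusted p under 0.05. The 12 highest were PLEK2 (8.64), MALL, THBD, which encodes thrombomodulin (7.87), PRSS3, a trypsin (7.26), PAEP (7.13), GNA15 (7.08), CXCL8, CCNC (6.47), IGFBP4, CDCP1, a transmembrane substrate of Src (6.31), SERPINB9 (6.28) and CD109 (6.26). The 12 lowest were GJA1, ALDH1A1, SPP1, which encodes osteopontin (-8.95), the neurofilament gene NEFH (-8.23), SOX2, MAP2 (-7.92), the nuclear receptor gene NR2F1 (-7.73), COL5A2 (-7.49), SKIDA1 (-7.27), ARID5B (-7.25), PRDX2 (-7.19) and MYL9 (-7.13). Leaving out any single array of the 4 left 0 genes on either side by limma, with 4190, 3094, 1275 and 1370 genes at an unadjusted p under 0.05 without the CL1-5 control, knockdown, vector and HA-G9a arrays. With a mean-variance trend limma gave 665 and 344, and without a filter on dim genes 8 and 9.

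Among the lists in this comparison, immediate early and AP-1 genes had a median difference of 1.20, with 3 of 21 higher and 0 lower over all genes by limma and 9 higher and 2 lower adjusted over the list alone; DUSP4 differed by 5.95 and DUSP5 by 5.16. Integrins and laminins had 1 of 17 higher and 0 lower, and 7 higher and 1 lower adjusted over the list alone, with ITGA6 at 4.35. Metallothioneins had 0 of 6 past the threshold over all genes and 6 higher adjusted over the list alone, with a median of 3.01 and all sharing closely related probe sets. NF-kB cytokines had 3 of 15 higher and 0 lower, and 5 higher and 0 lower adjusted over the list alone, with IL6 at 5.32 and CXCL1 at 3.72. Interferon-stimulated genes had 2 of 30 higher and 0 lower, and 7 higher and 0 lower adjusted over the list alone. Mesenchymal genes had 1 of 28 higher and 5 lower, and 6 higher and 6 lower adjusted over the list alone. The list median was 0.83 (percentile 99.99), while COL5A2, WNT5A (-6.15) and TWIST1 (-5.44) were lower. Median and tested members did not point the same way, so no direction is given for the list. SNAI2 differed by 4.78 (limma adjusted p = 0.0686).

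CL1 invasion genes had 1 of 6 higher, CXCL8, and 1 lower, CRMP1 (-5.73), with 3 and 3 adjusted over the list alone; CRMP1 was named in earlier work on these lines as an invasion suppressor. Epithelial genes had 2 of 25 higher, DSP (3.58) and DSG2 (2.76), and 2 lower, JUP (-2.70) and SPINT2 (-2.66), with 3 and 6 adjusted over the list alone. Proteases had 1 of 23 higher and 1 lower, TFPI2 (-5.29), with 3 and 2 adjusted over the list alone. Hypoxia genes had 3 of 23 higher, among them ENO2 (5.08) and NDRG1 (4.33), and 1 lower, SLC2A3, a glucose transporter (-5.62), with 6 and 4 adjusted over the list alone. REST-repressed neuronal genes had 0 of 20 higher and 3 lower, NEFH, CHGA (-2.57) and BEX1 (-2.44), with 0 and 4 adjusted over the list alone. The median of that list was -0.83, below all random lists. Serine, glycine and ATF4 targets had a median of -0.95, also below all random lists, with 0 of 23 past the threshold over all genes or adjusted over the list alone. Among type II alveolar markers 1 of 12 was higher, FOXA2 (6.11), with 2 higher adjusted over the list alone. The cell cycle list had 1 of 32 higher, CCND1, cyclin D1 (4.55), with 2 adjusted over the list alone, and the p53 list 1 of 18 higher, SERPINB5, maspin (5.08), with 2 adjusted over the list alone. TGF-beta and YAP targets had 0 of 20 higher and 2 lower, including CCN2 (-4.44), with 2 and 2 adjusted over the list alone. The Wnt list had 0 of 13 higher and 1 lower, WNT5A, with 4 and 3 adjusted over the list alone, and the xenobiotic list 0 of 20 higher and 1 lower, ALDH1A1, with 0 and 1 adjusted over the list alone. By limma, 0 of 26 genes of the H3K9 and DNA methylation machinery and 0 of 13 cancer-testis genes passed over all genes or adjusted over the list alone.

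A limma model with cell line and G9a arm, comparing the CL1-5 control and HA-G9a arrays with the knockdown and vector arrays, left 1 residual degree of freedom. It called 0 genes, with 691 genes at an unadjusted p under 0.05 and a smallest limma adjusted p of 0.833. Robust limma called 0, with 670 at an unadjusted p under 0.05, and limma with a mean-variance trend called 61. Of these, 39 were higher and 22 lower on the array of each line with more G9a. On simulated data the model recovered 0 of 50 genes at every size tried. The simulated noise was the spread within the lines, which includes the effects of changing G9a, so recovery may be understated. Neither the simulation nor the count of 0 tells whether genes differed.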

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

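All tests reported here were chosen only after the results had been seen. Genes were singled out when the knockdown in CL1-5 and HA-G9a in CL1-0 moved them at least 2-fold the same way, since the 2 changes of G9a are opposite; only genes past the stricter filter were considered, and the difference between the lines was not tested. There were 15 such genes, 13 higher in both and 2 lower in both. NRG1, a ligand of ERBB3, had relative log2 ratios of 5.00 after the knockdown and 1.84 with HA-G9a, and the long noncoding RNA UCA1 of 3.47 and 2.69. F2RL2 had 5.64 and 1.09, GPAT3, a glycerol-phosphate acyltransferase, 2.35 and 1.43, PTPRK, a receptor phosphatase, 2.41 and 1.14, and FOXQ1, a forkhead factor, 2.06 and 1.18. VCX2 had 1.78 and 1.26, LCORL 1.41 and 1.42, CLU, which encodes clusterin, 1.41 and 1.01, ELL2, an elongation factor, 1.40 and 1.03, NRCAM, a neuronal adhesion molecule, 1.26 and 1.30, the probe set annotated to MIR3682, which reads a longer transcript and not the mature microRNA, 1.12 and 1.14, and MGST1, a microsomal glutathione transferase, 1.12 and 1.80. Lower in both were CYBRD1, a ferric reductase, with -3.42 and -1.09, and MFAP2, a microfibril protein, with -3.004 and -1.23.

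Apart from the array's control probe sets, 11721 probe sets were not named by the annotation table used here. Of the 896 past the stricter filter in CL1-5, 7 were at least 4-fold higher after the knockdown relative to the median gene, beside 82 of 8458 named genes. Of the 777 past it in CL1-0, 2 were at least 4-fold higher with HA-G9a, beside 27 of 7743 named genes. They were singled out because they belong to no gene in the comparisons; 4 were at least 4-fold lower after the knockdown and 0 with HA-G9a.

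Genes far brighter in CL1-5 than in CL1-0 were often brighter in CL1-0 with HA-G9a. CL1-5 cells in the HA-G9a culture would add the same share of each CL1-5 signal, but of 23 genes with a mean CL1-5 signal of at least 300 and below the filter with the vector, 47.8% gained under 0.5% of it while the 75th percentile of the gain was 4.18%; MALL and PLEK2 gained almost nothing. Dim signals that can only go up would raise genes dim in both lines alike, yet 34.8% of 138 genes dim in CL1-0 and bright in CL1-5 were 2-fold higher against 23.3% of 1081 genes dim in both, a difference of 11.5 points (95% counting interval 3.13 to 19.8). Of the same genes, 7.25% and 17.9% were 2-fold lower. The interval treats genes on 1 pair of arrays as independent, which they are not, so it measures no spread between cultures. No biological explanation was tested. Chance divergence of 1 transduced population stays open, since no second HA-G9a array was analysed here.

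Interferon-stimulated genes were lower after the knockdown. Array scaling was argued against: it would move members like all genes of the same brightness, but their log2 ratios minus those of such genes had a median of -2.69 (quartiles -3.41 and -0.985). A dependence on G9a would raise the list with HA-G9a; its median there was 0.30, at percentile 99.3 of random lists, but 15.0% of members were 2-fold higher, so the test did not decide. An interferon response in the control shRNA culture may also be the source: over the 29 members the control array lay 2.76 above the CL1-0 vector array on the log2 scale and the knockdown array 0.77 above it. These explanations cannot be told apart, because no CL1-5 array without a hairpin was analysed here.

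More genes were past 2-fold after the knockdown than with HA-G9a; the difference was not tested. CL1-0 cells in the knockdown culture were argued against: 27 genes bright in CL1-0 and dim in the CL1-5 control gained a median of 0.030% of their CL1-0 signal. Endothelial cells in the CL1-5 control culture could not be excluded as a candidate source of PECAM1, at 318, CLDN5, CDH5, ERG, at 35.2, and KDR, at 17.2. The brighter of VWF and TEK read 1.97 there, but neither probe set was bright on any of the 4 arrays, so this decides nothing; the puromycin selection named in the labels would remove untransduced cells of another type. Divergence of the stably transduced populations rather than G9a could give such differences too, and with 1 population carrying a G9a hairpin it cannot be told apart from an effect of G9a. The bright EHMT2 probe set had a larger relative change in the knockdown, -4.16 against 1.12, which was not tested as the reason. Its dimmer probe set had log2 ratios of -1.78 and 0.22 as deposited.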

How the results depend on the processing

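The processing was varied over scaling, floor, filter, probe-set choice, threshold and model. Of the log2 ratios of named genes under other settings, 395 kept their direction and lay within 1 SD between probe sets of a gene (0.54 after the knockdown, 0.51 with HA-G9a) of the value reported, 152 kept their direction and lay farther away, and 6 reversed. Of list medians, 310 lay within that SD divided by the square root of the members, and 48 farther away. The cause was not tested unless a cause is given. MAS5 signals near background limit the dim genes most, and counts depend on how many of them are kept.

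Scaling removed the general rise on the knockdown array by construction, whether it came from the array or from the cells. With each array scaled to the same median, 950 genes were 2-fold higher and 1081 lower after the knockdown, and 57 were higher after it and lower with HA-G9a. Quantile normalization gave 946, 1058 and 47, and 121 genes lower after the knockdown and higher with HA-G9a. Named ratios depended on the floor and on the choice of probe sets: a doubled floor moved 59 of 94 past that SD, a halved floor 28 and the mean over probe sets 50. Median scaling, which moved 0 of the 94, could hardly move a ratio taken relative to the median gene. A doubled floor gave 355 genes higher and 264 lower in CL1-5 by limma, and a halved floor 145 and 164.

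Without a filter, where more dim genes are counted, 1018 genes were lower after the knockdown, 1224 higher and 1095 lower with HA-G9a, 218 higher then lower and 138 lower then higher; limma called 8 higher and 9 lower in CL1-5. With the 75th percentile filter, which keeps fewer genes, 1034 were higher and 252 lower after the knockdown, 102 and 94 with HA-G9a, 12 higher then lower and 19 lower then higher, and limma called 363 higher in CL1-5. This filter together with median scaling, a setting added after the data had been seen, gave 377 higher after the knockdown, 86 higher and 122 lower with HA-G9a, 8 higher then lower, 23 lower then higher, and 401 higher in CL1-5 by limma.

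The mean over all probe sets gave 397 genes higher and 363 lower with HA-G9a, 52 higher then lower and 45 lower then higher. The EHMT2 log2 ratio after the knockdown was -1.62 there, since the mean includes its dim probe sets, and GAD2 reversed to 0.0527 with HA-G9a. Without probe sets of types _s_at and _x_at, C21orf58 reversed to 0.59 with HA-G9a. The values of ZNF771 (0.19), TMT1A (0.085) and OVOL2 (0.085) with HA-G9a, and of OVOL2 (-0.45) after the knockdown, were of the other sign there only because the remaining probe set was at or near the floor and the median gene was subtracted, so they measure no change. EPCAM has no other probe set.

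By construction, a 1.5-fold threshold gave more genes: 4896 higher and 1006 lower after the knockdown, 1214 and 1492 with HA-G9a, 525 higher then lower and 183 lower then higher. A 3-fold threshold gave fewer: 828 and 366, 307 and 228, 18 and 21.

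With a mean-variance trend, limma called 61 genes between the arrays of each line with more and less G9a, and 665 higher and 344 lower in CL1-5. With the arm in the model, which leaves 1 residual degree of freedom, limma called 120 and 134. Leaving out each array in turn, added after the data had been seen, left 0 to 0 genes higher and 0 to 0 lower by limma, with 1 residual degree of freedom and the lone array of a line assumed to vary like the other line. The 2 control arrays alone, with no test, gave 1615 higher and 1732 lower at 2-fold.

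The EHMT2 log2 ratio with HA-G9a, 1.04 as deposited, was 0.963 under median scaling and 0.799 for the mean over probe sets, below 2-fold in both, and 1.09 after quantile normalization. EHMT2 otherwise stayed between -4.15 and -3.74 after the knockdown, and EPCAM between 1.16 and 1.58 after it and between -1.04 and -0.97 with HA-G9a.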

Other observations

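All tests behind the values below were chosen after the data had been seen. A few genes of the EGF ligands and receptors were picked after their values had been seen; the family was not tested as a list. After the knockdown NRG1 read 411 against 9.60 and EREG 32.3 against 1.46, while HBEGF read 223 against 1587. ERBB3, the receptor that NRG1 binds, read 13.3 against 0.67 after the knockdown, and with HA-G9a 8.56 against 50.3, dim signals throughout.

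Across genes past the stricter filter in both lines, the HA-G9a ratio correlated with the difference of CL1-5 from CL1-0 with r = 0.18, and the knockdown ratio with r = 0.01; genes are not independent replicates. Each ratio shares its arrays with the line difference, so noise that is unequal between the arrays of a line can add to these values, and their size is not read further.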
